A study of Oryza sativa with 8 samples.

How the data were processed

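Gene expression was measured by RNA-seq of polyadenylated RNA from seedlings of 2 rice genotypes in 2 orientations, with 2 libraries per group and 8 libraries in all. Libraries were made with a NEBNext Ultra kit, per the labels' protocols. Reads were aligned with TopHat2 2.0.12 and Bowtie2 2.2.3 to the IRGSP-1.0 genome and counted per gene with HTSeq 0.6.1, per the submitters' processing notes. The authors deposited a table of 38133 gene rows with whole-number read counts per gene and library, not normalized. The same table holds FPKM values that the authors made from the counts. Tested on the file, the FPKM of a gene was its count per kilobase of gene length, scaled by the library total and a constant for each library. The authors' deposited table also holds log2 fold changes for genotype and orientation, and p-values with adjusted p-values for the same comparisons. The tool behind these comparisons is not given in the sources used here. Columns of group means, 8 in number, were not used. Gene names and descriptions were taken from the table, which gives a name for 10796 of 38133 genes and includes 1289 gene models added by the authors. Whether the counting used strand, and how reads with several places were treated, is not given in the sources used here, so overlapping and antisense genes and members of near-identical families are uncertain, the 2 ribonuclease genes, the metallothioneins and the momilactone synthases among them.

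Each library was assigned to its group from its label. The total count per library ranged from 15294666 to 16723495. edgeR 4.0.16 in R 4.3.3 was run on the counts as deposited. Genes were kept with filterByExpr by group, which left 25317, libraries were scaled by TMM (factors 0.941 to 1.03), and 1 quasi-likelihood model with a mean per group was fitted to all 8 libraries, which leaves 4 residual degrees of freedom and lets the groups share 1 estimate of spread. The contrasts were bta3-1 against WT in vertical and in horizontal seedlings, horizontal against vertical in WT and in bta3-1, and the interaction, which is the orientation effect in bta3-1 minus that in WT. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 by edgeR's quasi-likelihood F test. Standard errors of log2 fold changes are the fold change divided by the square root of F. Levels are CPM on TMM-scaled library sizes, with the SD over n = 2. A prior count of 2 was used for log2 CPM in correlations and components. A group at 0 counts was given a floor of 3 counts per library, and groups with 1 to 3 counts a count ratio with a 95% counting interval.

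Of 36 gene lists written as text patterns over names and descriptions, 35 had at least 5 members tested. They were tested with camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation, and no list passed in that form. A call by camera therefore rests on the preset value. Counts of members are given over all genes tested and adjusted over the list alone. The groups, tests, gene lists, alternatives and the rule for named genes were set before the data were examined. That rule took, per comparison, genes past the threshold whose replicates did not overlap, with a mean log2 CPM of at least 1 and an informative name. Among them it named the 6 with the largest rise, the 6 with the largest fall, 5 others with the lowest adjusted p, the 3 leading members of each called list, and LAZY 1 in any case. Genes printed outside it (GIBBERELLIN 20-OXIDASE 1 for orientation, the root-specific genes and members of the tiller angle list) were chosen after their values were seen or to describe a list.

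The alternatives were DESeq2 1.42.0, DESeq2's size factors in edgeR, no filter on low counts, only the 4 libraries of a contrast, the replicate number as a block, robust dispersion, limma-trend on log2(FPKM + 1), a log2 fold change of at least 1, an adjusted p of 0.01 for overlaps, and leaving out each library in turn. With 1 library left in a group, that library was assumed to vary like the other groups. Results without the windows of 1 Mb crowded with genotype calls and without genes absent from a genotype (3 counts or fewer over its 4 libraries, more than 100 in the other), in which the same p-values were adjusted anew over the genes left, and lists freed of potassium channels were added after the data were seen. The tests were tried on simulated counts for the vertical genotype comparison over 24880 genes, 200 of them changed. The changed genes were drawn from those with a mean CPM above 1 on the log2 scale. Counts were drawn independently for each gene and library, without a shift shared by replicate number. edgeR recovered 15% of genes changed 2-fold and 82% of genes changed 4-fold, with 6.73% of 104 calls false, and DESeq2 recovered 48% and 86%, with 21.2% of 170 calls false. limma-trend, run here on log2(CPM + 1) over 25317 genes, recovered 17% and 78%, with 9.52% of 105 calls false. With nothing changed in the horizontal genotype comparison, edgeR made 3 calls over 24880 genes. The level of BTA3 is not reported here, and sequence-based checks such as GC content were not run because no genome was used here.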

Results

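Gene expression was measured by RNA-seq in 8 libraries from 7-day-old rice seedlings of the wild type (WT) and of the mutant bta3-1. BTA3 is named by the series as a gene that sets how wide tillers stand and how the shoot bends with gravity. Seedlings of each genotype either stood upright for all 7 days or stood upright for 4 days and were then laid horizontally for 3 days. The 4 groups held 2 libraries each, and the series describes them as biological replicates. Total gene counts were 15294666 and 15978482 in vertical WT, 16723495 and 15761846 in vertical bta3-1, 15752320 and 15309493 in horizontal WT, and 15419012 and 16172684 in horizontal bta3-1, in order of replicate. The 10 genes with most reads took 5.09% to 6.25% of a library. Log2 CPM, counts scaled to the library total, correlated between the libraries of a group with Pearson's r of 0.958 in vertical WT, 0.973 in vertical bta3-1, 0.971 in horizontal WT and 0.970 in horizontal bta3-1, across genes, which are not independent replicates. No pair of libraries agreed within sampling noise, since the chi-square per degree of freedom within groups was 31.0, 14.9, 17.5 and 16.1 in the same order. The p-values measure the spread between these samples.

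The 8 libraries separated by genotype and by orientation. The component with most variance (38.1%) placed the WT libraries between -75.6 and -38.2 and the bta3-1 libraries between 39.5 and 69.1. The next component (25.7%) placed the vertical libraries between 31.1 and 51.8 and the horizontal libraries between -63.4 and -15.8. The third (13.4%) separated the replicate numbers, with the replicate 1 libraries between 15.5 and 41.8 and the replicate 2 libraries between -50.1 and -4.88.

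**Figure D1:**
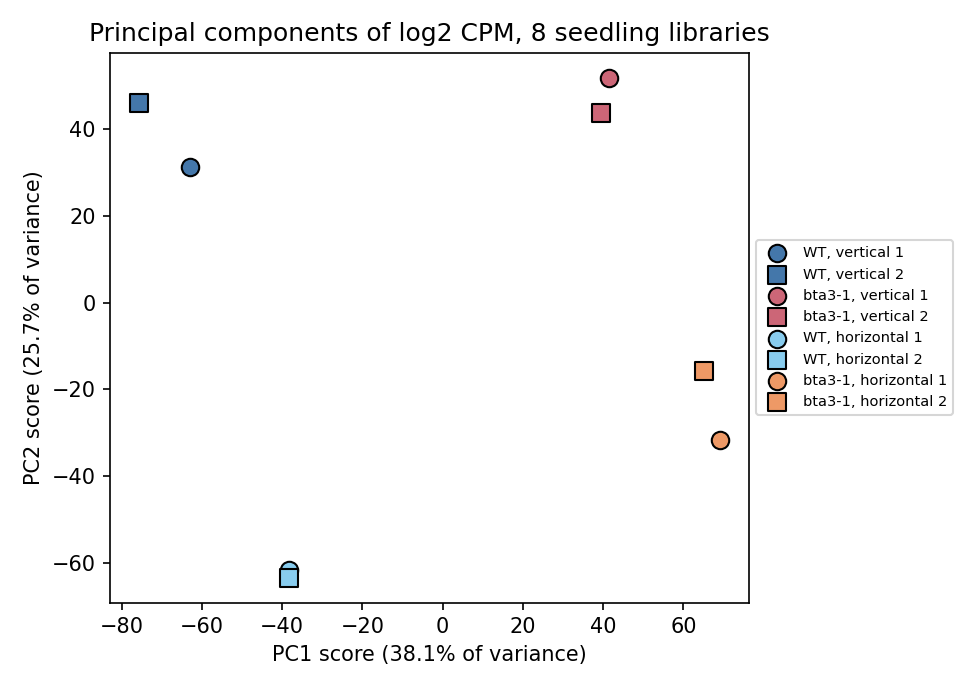
Principal components of log2 CPM over the genes tested, with PC1 (38.1% of the variance) on the x axis and PC2 (25.7%) on the y axis, both in component units, and 1 point per library. WT and bta3-1 lie on opposite sides of 0 on PC1, and vertical and horizontal libraries on opposite sides of 0 on PC2.

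The series asks how BTA3 acts on tiller angle and shoot gravitropism, so known regulators of these traits were read before any wider comparison. LAZY 1 (Os11g0490600; chromosome 11, 17318918 to 17324441, plus strand, IRGSP-1.0), a gene needed for normal shoot gravitropism in rice, fell in WT when seedlings were laid horizontally. Its level was 73.01 ± 9.65 CPM (SD, n = 2) in vertical WT and 31.6 ± 5.95 in horizontal WT, a log2 change of -1.21 (SE 0.222, edgeR adjusted p = 0.0222). In bta3-1 it stood at 37.8 ± 1.67 CPM in vertical and 22.99 ± 6.11 CPM in horizontal seedlings (log2 change -0.72, edgeR adjusted p = 0.174). This change in bta3-1 passed in edgeR with the replicate number as a block (adjusted p = 0.0294) and missed the threshold with DESeq2 (0.136). Between genotypes, the log2 difference of bta3-1 from WT was -0.95 (SE 0.22, edgeR adjusted p = 0.0886) in vertical seedlings, which missed the threshold, and -0.46 (adjusted p = 0.424) in horizontal seedlings. The vertical genotype difference passed with DESeq2 (adjusted p = 0.0098) and in edgeR with the replicate number as a block (0.00969). It missed the threshold in every other setting, among them all the fits that left out 1 library. Outside those fits, the adjusted p was 0.0501 to 0.122. In the fits that left out 1 library, this difference was -1.09 to -0.80. The test of whether the orientation effect on LAZY 1 differed between genotypes missed the threshold (interaction log2 0.49, adjusted p = 1). Its call in WT was lost without vertical WT replicate 2 (adjusted p = 0.0987), without horizontal WT replicate 1 (0.149), without horizontal WT replicate 2 (0.0869) and when only the 4 WT libraries were fitted (0.0563). Of 9 table entries matched to the list of tiller angle and shoot gravitropism regulators, 6 were expressed enough to test, and LAZY 1 was the 1 member called, in WT for orientation. TILLER ANGLE CONTROL 3 (Os03g0726700) lay at 0.956 ± 0.438 CPM in vertical WT and 0.860 ± 0.361 CPM in vertical bta3-1, and DEEPER ROOTING 1 (Os09g0439800), a LAZY-family gene of root angle, at 2.49 ± 0.504 and 1.80 ± 0.273 CPM. HOMEOBOX GENE 1 (Os10g0561800) lay at 35.1 ± 6.45 CPM in vertical WT and 27.2 ± 0.713 CPM in vertical bta3-1, and indeterminate domain 14 (Os03g0237250) at 7.02 ± 0.240 and 4.44 ± 0.142 CPM. All 6 members had a negative log2 difference of bta3-1 from WT in vertical seedlings (median -0.41), with 1 lower adjusted over the list alone. In horizontal seedlings 4 were negative and 2 positive. The list was not called by camera in vertical seedlings (adjusted p = 0.136, and 0.805 with an estimated correlation). No gene in the table carries the name BTA3, so the level of the mutated gene is not reported here.

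**Figure D2:**
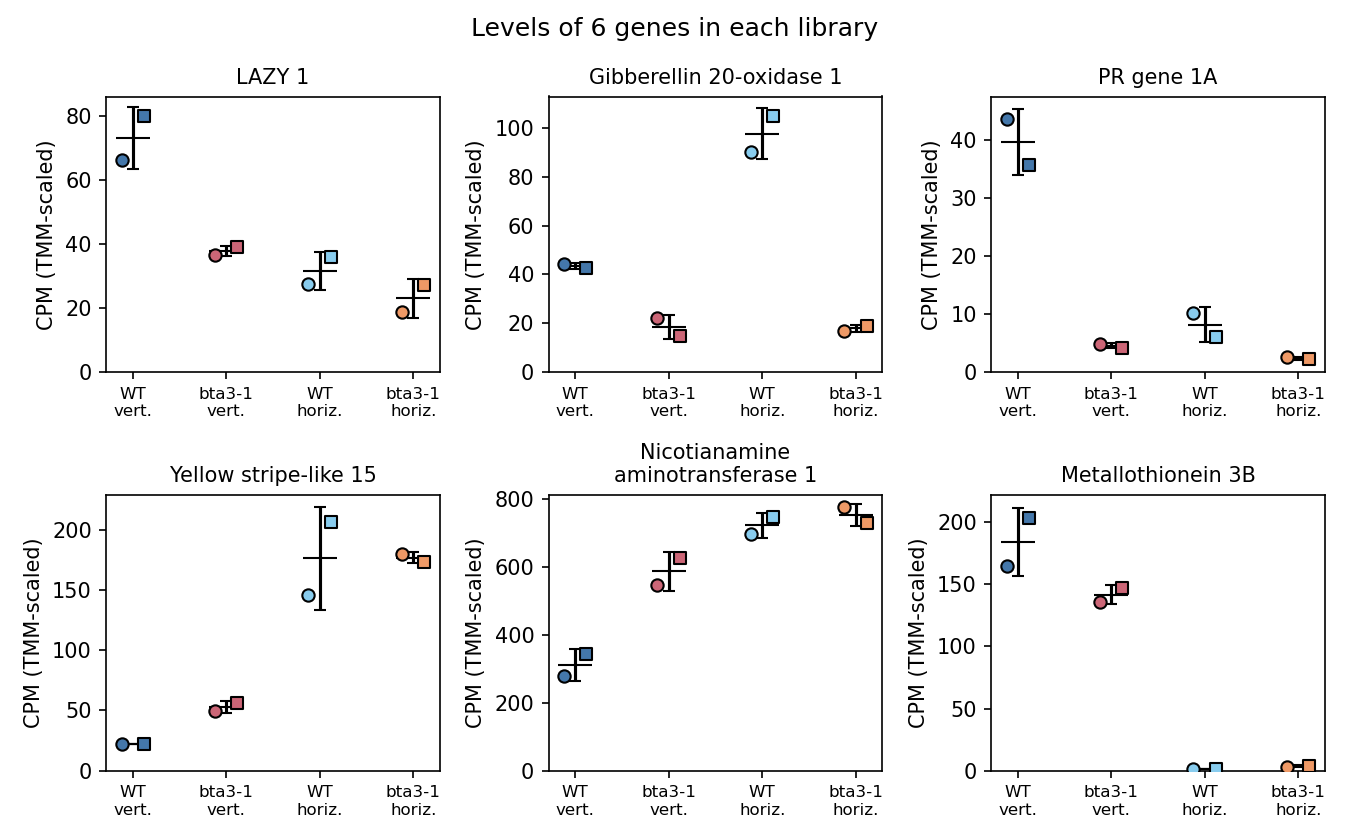
Levels of 6 genes in TMM-scaled CPM (y axis, linear, 1 panel per gene) in the 4 groups (x axis), with 1 point per library, circles for replicate 1, squares for replicate 2, and a line at each group mean with error bars of 1 SD (n = 2). LAZY 1 goes from 73.01 CPM in vertical WT to 31.6 CPM in horizontal WT, and METALLOTHIONEIN 3B from 184 to 1.26 CPM.

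In vertical seedlings, bta3-1 had lower transcripts than WT of single genes of gibberellin synthesis and defence, and higher transcripts of an iron transporter. GIBBERELLIN 20-OXIDASE 1 (Os03g0856700; chromosome 3, 36150664 to 36152355, plus strand), an enzyme of gibberellin synthesis, was at 43.4 ± 1.13 CPM in WT and 18.5 ± 5.06 CPM in bta3-1 (log2 -1.23, SE 0.204, edgeR adjusted p = 0.0196, n = 2 per group). PATHOGENESIS-RELATED GENE 1A (Os07g0129200; chromosome 7, 1512025 to 1512958), a defence marker, fell from 39.7 ± 5.66 CPM in WT to 4.52 ± 0.444 CPM in bta3-1 (log2 -3.13, SE 0.297, adjusted p = 0.000975). YELLOW STRIP-LIKE GENE 15 (Os02g0650300; chromosome 2, 26200136 to 26204468), a transporter of iron bound to phytosiderophores, rose from 21.9 ± 0.041 CPM to 52.6 ± 4.99 CPM (log2 1.26, SE 0.186, adjusted p = 0.0101). In all, 409 of 25317 genes tested passed, 166 higher and 243 lower in bta3-1, and 387 of them differed by at least 1 on the log2 scale.

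The gene lists described these differences in vertical seedlings further. Of 13 genes of gibberellin metabolism, 1 fell and none rose, with 0 higher and 3 lower adjusted over the list alone, and the list median was -0.74. The list was called lower by camera (adjusted p = 0.000567), but adjusted p = 0.234 with an estimated correlation. Of 7 genes of diterpenoid phytoalexin synthesis, the making of antimicrobial compounds, 2 fell, with 0 higher and 3 lower adjusted over the list alone (camera adjusted p = 7.79e-05; adjusted p = 0.413 with an estimated correlation). They were ENT-COPALYL DIPHOSPHATE SYNTHASE 4 (Os04g0178300), at 37.1 ± 10.4 CPM in WT and 1.81 ± 0.0735 CPM in bta3-1 (log2 -4.35, SE 0.607), and MOMILACTONE A SYNTHASE (Os04g0179200; log2 -1.75, SE 0.328), both on chromosome 4. Of 109 pathogenesis-related genes, 6 fell and 3, all chitinases, rose, with 4 higher and 19 lower adjusted over the list alone (camera adjusted p = 0.00329; adjusted p = 0.805 with an estimated correlation). PATHOGENESIS-RELATED GENE 10B (Os12g0555200) fell by 2.56 on the log2 scale (SE 0.445), and ETHYLENE RESPONSE FACTOR 48 (Os08g0408500) by 1.05 (SE 0.146). The latter is a transcription factor that the list took in because 15 of its members are annotated as pathogenesis-related transcriptional factors, and such factors are not themselves defence proteins. Of 58 jasmonate pathway genes, 4 fell, with 3 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.000702; adjusted p = 0.753 with an estimated correlation). They included 12-OXOPHYTODIENOATE REDUCTASE 4 (Os06g0215900), which fell by 7.71 on the log2 scale (SE 0.549, adjusted p = 0.000191), and a lipoxygenase LH2 domain protein (Os10g0361000), which fell by 7.23 (SE 0.341). The list also held 4 potassium channels matched by an accident of spelling. Without them it kept 54 members, 3 of them lower, at a camera adjusted p of 0.0231.

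Of 18 iron homeostasis genes in vertical seedlings, 3 rose and none fell in bta3-1, with 7 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.000446; adjusted p = 0.234 with an estimated correlation). Beside YELLOW STRIP-LIKE GENE 15, these were NICOTINAMINE AMINOTRANSFERASE 1 (Os02g0306401; 311 ± 46.3 CPM in WT and 587 ± 56.9 CPM in bta3-1, log2 0.91) and NICOTIANAMINE SYNTHASE 2 (Os03g0307200; 497 ± 141 and 1338 ± 220 CPM, log2 1.43), enzymes of phytosiderophore synthesis. Among 21 root markers, 2 fell, a gene named root-specific RCc3 (Os02g0662000; log2 -5.18) and a root-specific PR10 gene (Os12g0555000; log2 -1.90), and the root marker list itself was not called. The call of RCc3 (highest adjusted p = 0.362) stood without vertical WT replicate 1 and in none of the other 7 fits that left out 1 library, and that of the PR10 gene (0.328) stood without either horizontal WT library and in none of the other 6. Of 149 cytosolic ribosomal protein genes, 15 had a negative log2 fold change, the median was 0.19, and 1 was called, 60S ribosomal protein L44 (Os07g0523700; log2 1.87). This list was called higher (camera adjusted p = 7.79e-05; adjusted p = 0.839 with an estimated correlation), with 0 called adjusted over the list alone.

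The largest genotype differences in vertical seedlings were genes read in a single genotype. An inwardly rectifying potassium channel gene (Os12g0118400; chromosome 12, 891782 to 898384) was at 72.5 ± 6.27 CPM in WT and at 0 counts in bta3-1, at least 395-fold lower against a floor of 3 counts per library. A transposase fragment (Os06g0226000) was at least 344-fold lower, and a RING-type zinc finger gene (Os10g0172600) at least 213-fold lower. In the other direction, a signal peptide peptidase-like gene (Os02g0825600; chromosome 2, 35452188 to 35459895) was at 33.4 ± 9.87 CPM in bta3-1 and at 0 counts in WT, at least 170-fold higher. An aldehyde oxidase gene (Os10g0138100) was at least 106-fold higher, and a cytochrome P450 gene (Os11g0635500) at least 84.1-fold higher. Floors and count ratios cover counting error alone. Among genes read in both genotypes, non-specific lipid transfer protein 1.16 (Os12g0114800; chromosome 12, 727802 to 728559) went from 1320 ± 393 CPM in WT to 10.9 ± 1.87 CPM in bta3-1 (log2 -6.92, SE 0.268, edgeR adjusted p = 2.47e-05). A cytochrome P450 gene (Os06g0204100) went from 0.164 ± 0.043 to 81.6 ± 5.64 CPM (log2 8.89). Its WT mean lay below the 0.194 and 0.200 CPM that 3 counts give in the vertical WT libraries, so this fold change is imprecise.

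These vertical genotype comparisons used edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The count of 409 was 180 without vertical bta3-1 replicate 1 and 176 without vertical bta3-1 replicate 2. Of 28 named genes called, 18 passed in all 8 fits that each left out 1 library and 10 did not. GIBBERELLIN 20-OXIDASE 1 lost its call without vertical WT replicate 1, vertical WT replicate 2 or vertical bta3-1 replicate 2 (highest adjusted p = 0.159). YELLOW STRIP-LIKE GENE 15 lost it without vertical WT replicate 2 or vertical bta3-1 replicate 2 (0.0981). ENT-COPALYL DIPHOSPHATE SYNTHASE 4 (0.104), ETHYLENE RESPONSE FACTOR 48 (0.112) and PATHOGENESIS-RELATED GENE 10B (0.242) lost it without either vertical bta3-1 library, the last also without vertical WT replicate 2. NICOTINAMINE AMINOTRANSFERASE 1 (0.207) and NICOTIANAMINE SYNTHASE 2 (0.246) lost it without vertical WT replicate 1, either vertical bta3-1 library or horizontal bta3-1 replicate 1, the latter also without horizontal bta3-1 replicate 2. MOMILACTONE A SYNTHASE (Os04g0179200; 0.289) kept its call in 2 of the 8 fits, those without horizontal WT libraries, and L44 (Os07g0523700; 0.277) in 1, the fit without vertical bta3-1 replicate 1. The jasmonate list was lost without vertical WT replicate 2 (0.0586), the ribosomal list without vertical WT replicate 1 (0.109), and the pathogenesis-related list without vertical WT replicate 2 or vertical bta3-1 replicate 2 (highest 0.0968). Fitting only the 4 vertical libraries ended the calls of GIBBERELLIN 20-OXIDASE 1 (0.0802), NICOTINAMINE AMINOTRANSFERASE 1 (0.114), NICOTIANAMINE SYNTHASE 2 (0.0772) and L44 (0.1). Leaving out the genes of the 18 crowded windows given with the genotype overlap ended those of the jasmonate list (0.17), NICOTIANAMINE SYNTHASE 2 (0.0524), MOMILACTONE A SYNTHASE (0.0552) and L44 (0.0538).

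In horizontal seedlings, bta3-1 again had lower GIBBERELLIN 20-OXIDASE 1 (Os03g0856700) than WT, with 97.6 ± 10.4 CPM in WT and 17.9 ± 1.32 CPM in bta3-1 (log2 -2.45, SE 0.21, edgeR adjusted p = 0.000512, n = 2 per group). Of the 13 gibberellin metabolism genes, 1 fell and none rose, with 0 higher and 3 lower adjusted over the list alone and a median of -0.73 (camera adjusted p = 0.00131; adjusted p = 0.482 with an estimated correlation). WALL-ASSOCIATED KINASE GENE 112 (Os10g0180800; chromosome 10, 5539743 to 5544578), of a family of receptor kinases tied to the cell wall, was at 83.8 ± 7.97 CPM in WT and at 0 counts in bta3-1, at least 440-fold lower. The non-specific lipid transfer protein 1.16 gene (Os12g0114800) fell from 808 ± 9.21 to 9.05 ± 0.486 CPM (log2 -6.48), and the lipoxygenase LH2 domain gene (Os10g0361000) fell by 5.90 on the log2 scale. A tetratricopeptide-like gene (Os02g0493300) rose (log2 5.67, SE 0.38), and the cytochrome P450 gene Os06g0204100 stood at 844 times its WT count (95% counting interval 288 to 4094). In all, 385 of 25317 genes passed, 167 higher and 218 lower in bta3-1, 359 of them by at least 1 on the log2 scale. Without the genes of the crowded windows given with the genotype overlap, 85 were higher and 73 lower, against 87 and 96 in vertical seedlings.

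Further lists were called by camera between genotypes in horizontal seedlings with few or no single genes past the threshold. Of 43 core histone genes, 4 had a positive log2 fold change, the median was -0.32 and none was called (camera adjusted p = 0.00418; adjusted p = 0.785 with an estimated correlation). Of 149 cytosolic ribosomal protein genes, 125 had a positive log2 fold change, the median was 0.21 and none was called (camera adjusted p = 0.000331; adjusted p = 0.785 with an estimated correlation). None of the 7 diterpenoid phytoalexin genes was called over all genes, and 0 were higher and 4 lower adjusted over the list alone (camera adjusted p = 0.00731; adjusted p = 0.785 with an estimated correlation). The count of 385 was 210 without horizontal WT replicate 1, 203 without horizontal WT replicate 2, 236 without horizontal bta3-1 replicate 1 and 169 without horizontal bta3-1 replicate 2. Of 18 named genes called, 17 passed in all 8 fits that left out 1 library, and Phosphoenolpyruvate carboxykinase (Os10g0204300) did not, without horizontal bta3-1 replicate 2 (adjusted p = 0.0536) or with robust dispersion (0.0922). The histone list was lost without horizontal WT replicate 2 or horizontal bta3-1 replicate 1 (highest adjusted p = 0.896). The ribosomal list (highest 0.328) and the diterpenoid list (highest 0.084) were lost without horizontal WT replicate 1 or horizontal bta3-1 replicate 2.

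Genotype calls were shared between orientations. Of the genes called in each, 253 were called in both in the same direction, 94 higher and 159 lower in bta3-1, and 1 was called in opposite directions. Independent lists of these sizes would share 1.09 higher and 2.09 lower. Both contrasts take the spread of a gene from the same fit, so the lists are not fully independent. Across all 25317 genes the log2 fold changes of the genotype contrasts correlated with Pearson's r of 0.741, across genes that are not independent replicates, and the contrasts share no libraries. The shared genes crowded on chromosome 10, which held 76 of them against 13.5 expected (Fisher's exact test, adjusted p = 3.1e-35), while chromosome 3 held 11 against 32.6 (adjusted p = 4.29e-05). Of 252 such genes placed on chromosomes 1 to 12, 130 lay in 18 windows of 1 Mb with a binomial adjusted p under 0.05. The Fisher's and binomial tests take genes as independent, which neighbouring genes need not be, so these p-values may be too small. Outside these windows 61 were higher and 61 lower in bta3-1, and within them 32 were higher and 98 lower. The lipid transfer protein (Os12g0114800), the potassium channel (Os12g0118400), WALL-ASSOCIATED KINASE GENE 112, the lipoxygenase LH2 domain gene and the signal peptide peptidase-like gene lie in these windows. The count of 253 was 158 without vertical bta3-1 replicate 1, 159 without vertical bta3-1 replicate 2 and 155 without horizontal bta3-1 replicate 2.

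**Figure D3:**
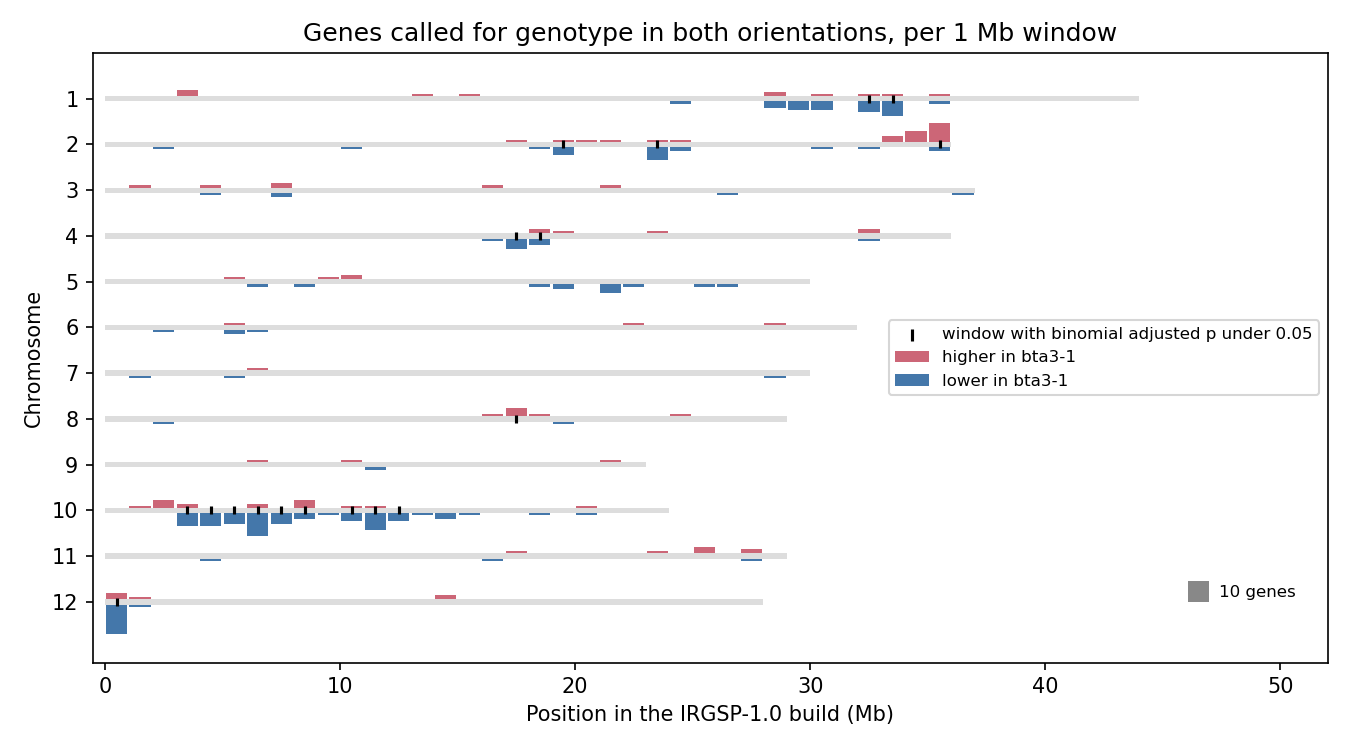
Genes called for genotype in both orientations along the chromosomes, per 1 Mb window, with position in Mb of IRGSP-1.0 on the x axis, chromosomes on the y axis, bar height the number of genes, red above the line for higher and blue below it for lower in bta3-1, and ticks at windows with a binomial adjusted p under 0.05. Chromosome 10 holds 76 of them against 13.5 expected from its share of the genes tested.

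Laying WT seedlings horizontally was followed by large falls of METALLOTHIONEIN 3B, ribonuclease and BURP domain genes and by rises of HEMOGLOBIN 2 and ALPHA-CARBONIC ANHYDRASE 3. METALLOTHIONEIN 3B (Os05g0202800; chromosome 5, 6393899 to 6396069, plus strand), a small metal-binding protein, fell from 184 ± 27.3 CPM in vertical to 1.26 ± 0.0838 CPM in horizontal WT (log2 -7.18, SE 0.249, edgeR adjusted p = 9.34e-06, n = 2 per group). RIBONUCLEASE 4 (Os09g0537700; chromosome 9, 21155963 to 21157945) fell from 815 ± 5.15 to 10.01 ± 4.02 CPM (log2 -6.35, SE 0.454), and the nearby RIBONUCLEASE 5 (Os09g0538000) fell by 5.56 on the log2 scale. BURP domain-containing genes Os05g0217800 (879 ± 56.9 to 38.3 ± 5.93 CPM, log2 -4.52) and Os06g0302000 (log2 -6.38) fell as well. HEMOGLOBIN 2 (Os03g0226200) rose from 0.623 ± 0.0333 to 29.1 ± 25.8 CPM (log2 5.53, SE 0.807), and ALPHA-CARBONIC ANHYDRASE 3 (Os08g0423500) rose from 0.233 ± 0.33 to 21.1 ± 2.28 CPM (log2 6.47, SE 0.659). In all, 1079 of 25317 genes passed, 311 higher and 768 lower in horizontal WT, and 811 differed by at least 1 on the log2 scale.

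Among lists that fell in horizontal WT, 22 of 109 pathogenesis-related genes fell and 1 rose, with 4 higher and 40 lower adjusted over the list alone (camera adjusted p = 2.64e-09; adjusted p = 0.241 with an estimated correlation). CHITINASE 9 (Os05g0399400) fell by 5.24 on the log2 scale, PATHOGENESIS-RELATED GENE 1A (Os07g0129200) by 2.28 and PATHOGENESIS-RELATED GENE 5 (Os12g0628600) by 2.04. Of 41 genes of abscisic acid and dehydration response, 7 fell and none rose, with 0 higher and 11 lower adjusted over the list alone and a median of -0.91 (camera adjusted p = 3.3e-07; adjusted p = 0.15 with an estimated correlation). RESPONSIVE TO ABA GENE 16A (Os11g0454300), a dehydrin, fell from 6.56 ± 0.323 to 0.916 ± 0.0406 CPM (log2 -2.83, SE 0.305), and ABSCISIC ACID-STRESS-RIPENING-INDUCIBLE 5 PROTEIN (Os11g0167800) from 1116 ± 46.3 to 506 ± 20.1 CPM (log2 -1.14). Of 74 lignin and phenylpropanoid genes, 12 fell and none rose, with 4 higher and 17 lower adjusted over the list alone (camera adjusted p = 0.0062; adjusted p = 0.241 with an estimated correlation). Cinnamoyl-CoA reductase (Os08g0441500; log2 -1.65) and coniferaldehyde 5-hydroxylase 1 (Os10g0512400; log2 -1.85), enzymes of monolignol synthesis, were among them. Of 153 heat shock genes, 13 fell and 1 rose, with 4 higher and 17 lower adjusted over the list alone (camera adjusted p = 0.0264; adjusted p = 0.309 with an estimated correlation), among them heat-shock protein 70 (Os01g0840100; log2 -2.14). Of 7 diterpenoid phytoalexin genes, 2 fell, with 0 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.00326; adjusted p = 0.241 with an estimated correlation). Of 10 auxin biosynthesis genes, 2 fell, among them YUCCA-LIKE GENE 5 (Os12g0512000; log2 -1.60), an enzyme of auxin synthesis (camera adjusted p = 0.0349; adjusted p = 0.241 with an estimated correlation). Of 21 xyloglucan endotransglucosylases, enzymes that remodel cell walls, 3 fell, with 0 higher and 5 lower adjusted over the list alone (camera adjusted p = 0.0264; adjusted p = 0.714 with an estimated correlation).

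Among lists that rose in horizontal WT, 6 of 18 iron homeostasis genes rose and 1 fell, with 7 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.000146; adjusted p = 0.15 with an estimated correlation). YELLOW STRIP-LIKE GENE 15 (Os02g0650300) rose from 21.9 ± 0.041 to 176 ± 42.7 CPM (log2 3.01, SE 0.195, adjusted p = 0.00032), and EFFLUX TRANSPORTER OF NICOTIANAMINE 1 (Os11g0151500) by 1.69 on the log2 scale. The member that fell is named NRR repressor homologue 3 and entered the list through a ferritin-like domain in its description. Of 20 Calvin cycle and RuBisCO small subunit genes, 5 rose and none fell, with 7 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.000146; adjusted p = 0.15 with an estimated correlation). RuBisCO small subunit 1 (Os02g0152400) rose by 1.25 on the log2 scale. A phosphoribulokinase/uridine kinase family gene (Os04g0596900) rose from 0.197 ± 0.0041 to 4.84 ± 1.32 CPM (log2 4.56). Of 22 hypoxia response genes, 3 rose, with 6 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.00837; adjusted p = 0.236 with an estimated correlation). HEMOGLOBIN 1 (Os03g0233900; log2 3.32) was among them. Of 99 cell cycle and DNA replication genes, 2 rose and 1 fell, with 0 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00583; adjusted p = 0.696 with an estimated correlation). Of 49 phosphate starvation genes, 2 rose, with 2 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.0495; adjusted p = 0.241 with an estimated correlation), PURPLE ACID PHOSPHATASE 1C (Os12g0576700; log2 1.69) and PHOSPHATE TRANSPORTER 1;3 (Os06g0493600; log2 1.32).

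For orientation in WT, the count of 1079 was 413 without vertical WT replicate 2, 222 without horizontal WT replicate 1, 143 without horizontal WT replicate 2, 614 without vertical bta3-1 replicate 1 and 600 without vertical bta3-1 replicate 2, and it was 346 when only the 4 WT libraries were fitted, where the same fit of the 4 bta3-1 libraries called 388. Of 45 named genes called, 21 passed in all 8 fits that left out 1 library, METALLOTHIONEIN 3B, both ribonucleases, both BURP genes, CHITINASE 9, PATHOGENESIS-RELATED GENE 1A and YELLOW STRIP-LIKE GENE 15 among them. HEMOGLOBIN 2 lost its call without vertical WT replicate 2 (adjusted p = 0.0574). Coniferaldehyde 5-hydroxylase 1 (0.0501), ABSCISIC ACID-STRESS-RIPENING-INDUCIBLE 5 PROTEIN (0.0644) and PATHOGENESIS-RELATED GENE 5 (0.0691) lost it without horizontal WT replicate 2. RuBisCO small subunit 1 (Os02g0152400) lost it without either horizontal WT library (highest 0.129), and PURPLE ACID PHOSPHATASE 1C (highest 0.0938) without these or vertical WT replicate 2. YUCCA-LIKE GENE 5 (highest 0.192) kept its call in the fits without a vertical bta3-1 library and lost it in the other 6. PHOSPHATE TRANSPORTER 1;3 (0.138) kept it in the fits without a horizontal bta3-1 library, and HEMOGLOBIN 1 (0.191) in those without vertical WT replicate 1 or vertical bta3-1 replicate 2. Of the members counted for the diterpenoid list, MOMILACTONE A SYNTHASE (Os04g0179200; adjusted p = 0.0498) passed in 0 of the 8 fits (highest 0.202) and was lost with DESeq2's size factors (0.0517). Of the 3 xyloglucan endotransglucosylases, Os06g0697000 (highest 0.177) passed in 1 of the 8, Os04g0631200 (0.203) in 2 and Os03g0239000 (0.129) in 5. Among the lists, auxin biosynthesis (highest 0.206) and xyloglucan endotransglucosylases (0.549) were lost without vertical WT replicate 2 or horizontal WT replicate 1. Cell cycle (0.171) was lost without vertical WT replicate 2, lignin (0.0634) without horizontal WT replicate 2, heat shock (highest 0.0699) without either of those, and diterpenoids (0.0528) and hypoxia (0.0819) without vertical WT replicate 1. Phosphate starvation was called in the fit without horizontal WT replicate 1 and in none of the other 7 (highest 0.127), and it was lost without the genes of crowded windows (0.0533). Fitting only the 4 WT libraries ended the calls of RuBisCO small subunit 1 (0.0806), HEMOGLOBIN 1 (0.0869), YUCCA-LIKE GENE 5 (0.0697), PURPLE ACID PHOSPHATASE 1C (0.0742), MOMILACTONE A SYNTHASE (0.124), the 3 xyloglucan endotransglucosylases (0.121, 0.114 and 0.075 in the order above) and PHOSPHATE TRANSPORTER 1;3 (0.0983), the last also lost with limma-trend (0.0528).

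**Figure D4:**
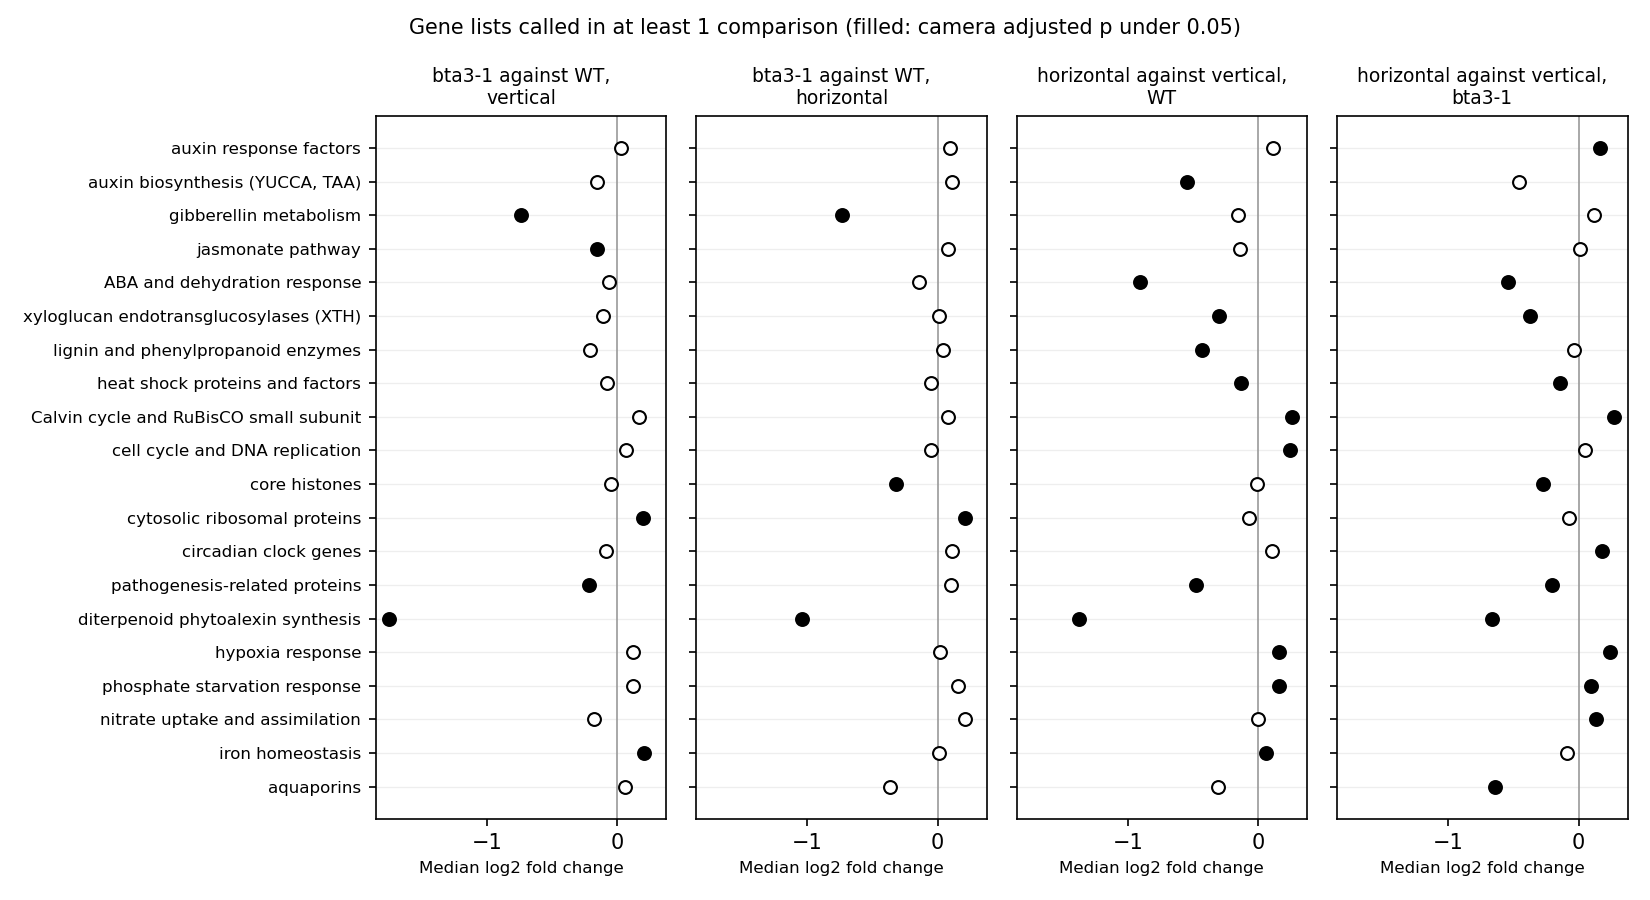
Median log2 fold change (x axis) of the gene lists called in at least 1 comparison (y axis), in 1 panel per comparison between groups, with filled points where camera's adjusted p is under 0.05. The list of abscisic acid and dehydration response has a median of -0.91 for orientation in WT and -0.54 in bta3-1, and gibberellin metabolism has -0.74 for genotype in vertical and -0.73 in horizontal seedlings.

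In bta3-1, laying seedlings horizontally was followed by falls of METALLOTHIONEIN 3B, RESPONSIVE TO ABA GENE 16A and an IAA-amino acid hydrolase gene and by rises of OsNIA1 and HEMOGLOBIN 1. METALLOTHIONEIN 3B (Os05g0202800) fell from 142 ± 7.6 to 3.32 ± 0.814 CPM (log2 -5.41, SE 0.223, edgeR adjusted p = 4.31e-05, n = 2 per group). RESPONSIVE TO ABA GENE 16A (Os11g0454300) fell from 12.8 ± 1.95 to 0.637 ± 0.115 CPM (log2 -4.32, SE 0.32, adjusted p = 0.00122). An IAA-amino acid hydrolase gene (Os03g0836800; chromosome 3, 35161307 to 35163174), of a family that releases auxin from conjugates, fell from 29.5 ± 0.329 to 0.412 ± 0.0289 CPM (log2 -6.13, SE 0.425, adjusted p = 0.00122). OsNIA1 (Os02g0770800), a nitrate reductase gene, stood at 152 times its vertical count (95% counting interval 41.7 to 1261), and HEMOGLOBIN 1 (Os03g0233900) at 39.1 times (13.03 to 192). In all, 281 of 25317 genes passed, 91 higher and 190 lower in horizontal bta3-1, 252 of them by at least 1 on the log2 scale.

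Of the 41 genes of abscisic acid and dehydration response, 5 fell and none rose in horizontal bta3-1, with 1 higher and 10 lower adjusted over the list alone (camera adjusted p = 4.39e-08; adjusted p = 0.159 with an estimated correlation). LATE EMBRYOGENESIS ABUNDANT 3-1 (Os05g0542500; log2 -4.73) and the EF-hand gene Os04g0511200 (log2 -4.96) were among the genes that fell. Of 153 heat shock genes, 7 fell and none rose, with 5 higher and 21 lower adjusted over the list alone (camera adjusted p = 0.00478; adjusted p = 0.258 with an estimated correlation). CYTOSOLIC HEAT SHOCK PROTEIN 70-1 (Os05g0460000) fell from 130 ± 25.7 to 30.1 ± 8.53 CPM (log2 -2.11, SE 0.225). Of 20 Calvin cycle and RuBisCO genes, 3 rose, with 6 higher and 0 lower adjusted over the list alone (camera adjusted p = 9.16e-06; adjusted p = 0.159 with an estimated correlation). They included RuBisCO small subunit 1 (Os02g0152400; log2 1.44) and Os08g0468100 (log2 3.00), which is named Rubisco activase but described as a nitrate reductase. Of 24 nitrate genes, 2 rose, with 3 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0158; adjusted p = 0.233 with an estimated correlation). Of 22 hypoxia genes, 1 rose, with 3 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.00466; adjusted p = 0.206 with an estimated correlation).

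Smaller list calls in bta3-1 followed the same contrast. Of 9 aquaporins, 2 fell and 1 rose, with 1 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.0404; adjusted p = 0.555 with an estimated correlation). Among them were the plasma membrane intrinsic protein genes Os02g0666200 (973 ± 124 to 553 ± 11.5 CPM, log2 -0.82) and Os04g0559700 (log2 -1.09). Of 109 pathogenesis-related genes, 2 fell, CHITINASE 9 (Os05g0399400; log2 -2.52) and an osmotin (Os03g0663400; log2 -1.83), and 1 rose, with 3 higher and 12 lower adjusted over the list alone (camera adjusted p = 0.0158; adjusted p = 0.642 with an estimated correlation). Of 7 diterpenoid genes, 1 fell, a momilactone A synthase gene model added by the authors (log2 -1.62; camera adjusted p = 0.0158; adjusted p = 0.375 with an estimated correlation). Of 21 xyloglucan endotransglucosylases, 1 fell (Os03g0239000; log2 -1.42), with 0 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.0158; adjusted p = 0.596 with an estimated correlation). Of 43 core histones, 1 fell, a histone H4 (Os09g0553100; log2 -0.88; camera adjusted p = 0.0118; adjusted p = 0.786 with an estimated correlation). Phosphate starvation genes (camera adjusted p = 0.028; adjusted p = 0.233 with an estimated correlation), circadian clock genes (0.018; adjusted p = 0.291 with an estimated correlation) and auxin response factors (0.0448; adjusted p = 0.555 with an estimated correlation) were called higher as lists, with 0 single genes called over all genes tested.

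For orientation in bta3-1, the count of 281 was 19 without vertical bta3-1 replicate 1, 85 without vertical bta3-1 replicate 2, 11 without horizontal bta3-1 replicate 1, 6 without horizontal bta3-1 replicate 2, 178 without horizontal WT replicate 1 and 172 without horizontal WT replicate 2. Of 31 named genes called, 6 passed in all 8 fits that left out 1 library. They were METALLOTHIONEIN 3B, RESPONSIVE TO ABA GENE 16A, the IAA-amino acid hydrolase, a BURP gene (Os06g0302000), PMEI8 (Os02g0537000) and Os02g0530100. The other 25 lost their calls without at least 1 of the 4 bta3-1 libraries, with a highest adjusted p of 0.379 for the osmotin (Os03g0663400), which passed in none of the 8 fits. OsNIA1 (highest 0.182), RuBisCO small subunit 1 (0.267) and LATE EMBRYOGENESIS ABUNDANT 3-1 (0.234) lost it without any of these 4. HEMOGLOBIN 1 (0.202) lost it without any of them or either horizontal WT library, and CYTOSOLIC HEAT SHOCK PROTEIN 70-1 (0.0662) without vertical bta3-1 replicate 1 or horizontal bta3-1 replicate 2. Robust dispersion ended the call of Os08g0468100 (0.053), limma-trend those of the aquaporin Os02g0666200 (0.051) and histone H4 (Os09g0553100; 0.05), and fitting only the 4 bta3-1 libraries that of the osmotin (0.0512). Among the lists, xyloglucan endotransglucosylases (highest 0.238), histones (0.394) and clock genes (0.0759) were lost without horizontal bta3-1 replicate 1, and diterpenoids (0.101) and phosphate starvation (0.102) without horizontal bta3-1 replicate 2. Pathogenesis-related genes (0.604) were lost without vertical or horizontal bta3-1 replicate 1, auxin response factors (0.122) without any bta3-1 library, and aquaporins (0.274) without 5 of the 8 libraries, namely either vertical WT library, vertical bta3-1 replicate 1 or either horizontal bta3-1 library.

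Orientation calls were shared between genotypes. In both, 212 genes were called in the same direction, 64 higher and 148 lower in horizontal seedlings, and 0 in opposite directions. Independent lists would share 1.12 higher and 5.76 lower, but both contrasts take the spread of a gene from the same fit. METALLOTHIONEIN 3B, BURP domain-containing Os05g0217800 and the gene named MPI (Os12g0548700; log2 -3.72 in WT) were among those that fell in both. Across all genes, the orientation log2 fold changes of WT and bta3-1 correlated with Pearson's r of 0.516, across genes that are not independent replicates. The count of 212 was 88 without horizontal WT replicate 1, 75 without horizontal WT replicate 2, 19 without vertical bta3-1 replicate 1, 71 without vertical bta3-1 replicate 2, 11 without horizontal bta3-1 replicate 1 and 6 without horizontal bta3-1 replicate 2.

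Whether orientation acted differently in bta3-1 than in WT was asked gene by gene with the interaction term of the model. With edgeR's quasi-likelihood test 0 of 25317 genes passed, with a smallest adjusted p of 0.091, and 1143 had an unadjusted p under 0.05 where 1266 are expected by chance. DESeq2 called 25, edgeR with the replicate number as a block called 8, edgeR without a filter on low counts called 3, and limma-trend called 0. The larger number of orientation calls in WT (1079) than in bta3-1 (281), which turned to 346 against 388 in fits of 4 libraries each, is therefore not shown by this test to be a difference between genotypes for any single gene. GIBBERELLIN 20-OXIDASE 1 (Os03g0856700) rose in WT when seedlings were laid horizontally (log2 1.17, edgeR adjusted p = 0.018). That call was lost without vertical WT replicate 2 or either horizontal WT library. In bta3-1 its level was 18.5 ± 5.06 CPM in vertical and 17.9 ± 1.32 CPM in horizontal seedlings. It did not pass edgeR's interaction test, so a response that differs between genotypes is not shown for it. The authors' deposited table called 648, 655, 1245 and 1013 genes for genotype in vertical, genotype in horizontal, orientation in WT and orientation in bta3-1, and it shared 396, 374, 907 and 278 genes with the counts given here, all with the same sign.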

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

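Of the tests in this part, those on root tissue and on the jasmonate list without potassium channels were chosen after the result was seen, and the tests of single genes against their libraries and of lists for interaction were planned.

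Several gene lists had an orientation effect that differed between bta3-1 and WT by the interaction test of camera. Positive medians mean a higher orientation effect in bta3-1. No list passed with an estimated correlation. Iron homeostasis genes had a lower effect in bta3-1 (median -0.60, adjusted p = 1.27e-07; adjusted p = 0.108 with an estimated correlation). Core histones (median -0.26, adjusted p = 0.00133; adjusted p = 0.982 with an estimated correlation) and cell cycle genes (median -0.14, adjusted p = 0.0206; adjusted p = 0.874 with an estimated correlation) were lower too. Pathogenesis-related genes (median 0.22, adjusted p = 3.15e-06; adjusted p = 0.782 with an estimated correlation), lignin enzymes (median 0.25, adjusted p = 0.000309; adjusted p = 0.363 with an estimated correlation), jasmonate genes (median 0.34, adjusted p = 0.00657; adjusted p = 0.782 with an estimated correlation), class III peroxidases (median 0.21, adjusted p = 0.00992; adjusted p = 0.874 with an estimated correlation) and nitrate genes (median 0.28, adjusted p = 0.0117; adjusted p = 0.363 with an estimated correlation) were higher. Without the potassium channels, the jasmonate list had an adjusted p of 0.00114. The iron and pathogenesis-related lists were also called for genotype in vertical seedlings and for orientation in WT. All these tests use the same vertical WT libraries, so the calls are not separate results. NICOTIANAMINE SYNTHASE 2 was at 497 CPM in vertical WT, 1338 in vertical bta3-1, 1701 in horizontal WT and 1741 in horizontal bta3-1. Vertical WT also had the lowest correlation within a group (0.958). The iron, pathogenesis-related and lignin lists passed in all 8 fits that left out 1 library. Jasmonate genes were lost without vertical WT replicate 2, vertical bta3-1 replicate 1 or horizontal bta3-1 replicate 2 (highest adjusted p = 0.424), peroxidases without vertical WT replicate 2 (0.671), and nitrate genes without vertical WT replicate 2, vertical bta3-1 replicate 1 or horizontal WT replicate 2 (0.199). Histones were lost without vertical WT replicate 1, horizontal WT replicate 2 or horizontal bta3-1 replicate 1 (0.979), and cell cycle genes without vertical WT replicate 2, vertical bta3-1 replicate 1, horizontal WT replicate 1 or horizontal bta3-1 replicate 2 (0.548).

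In 10 cases among 88 named genes, 1 for orientation and 9 for genotype, libraries did not overlap in either of the matching contrasts and moved in opposite directions. With 2 libraries per group such a pattern also arises by chance, and its share over all genes tested was not computed. The rule for named genes itself asked for replicates that did not overlap. The count of 10 is therefore not evidence of opposite responses. No gene of these passed the interaction test, so the differences are not shown by it. For orientation, ENT-COPALYL DIPHOSPHATE SYNTHASE 4 (Os04g0178300) was lower in horizontal than in vertical WT (log2 -1.66) and higher in bta3-1 (0.81), an interaction of 2.46 with an edgeR adjusted p of 1. For genotype, the interaction was 1.77 for METALLOTHIONEIN 3B (Os05g0202800; edgeR adjusted p = 0.652), 2.73 for CHITINASE 9 (Os05g0399400; 0.976), -1.49 for RESPONSIVE TO ABA GENE 16A (Os11g0454300; 1), 0.81 for ABSCISIC ACID-STRESS-RIPENING-INDUCIBLE 5 PROTEIN (Os11g0167800; 0.927) and 1.58 for coniferaldehyde 5-hydroxylase 1 (Os10g0512400; 0.767). It was 0.90 for 17.9 KDA CLASS I HEAT SHOCK PROTEIN 1 (Os03g0266300; 1), 0.94 for 17.9 KDA HEAT SHOCK PROTEIN 2 (Os01g0135900; 0.976), 3.88 for OsNIA1 (Os02g0770800; 1) and -1.40 for COPPER CHAPERONE HOMOLOG (Os02g0530100; 0.652).

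Of 18 iron homeostasis genes, 3 were called higher in vertical bta3-1 than in vertical WT, and 6 higher and 1 lower in horizontal than in vertical WT, and with an estimated correlation the list passed in neither (adjusted p = 0.234 and 0.15). A larger share of root tissue in the vertical bta3-1 samples, as a technical source, would raise root markers by about as much as the iron genes called higher. The median of 16 root markers was -0.0597 (upper quartile 0.18), below the lowest of these iron genes at 0.91. For the horizontal WT samples it was 0.14 (upper quartile 0.49), below the lowest of these at 1.20. These markers were matched by text, and many, RHD3 and katanin P60 among them, are not named as root-specific. Their median therefore cannot decide on the share of root tissue. Genes named root-specific had lower means than in vertical WT in both groups. In vertical WT, vertical bta3-1 and horizontal WT, RCc3 was at 20.3 ± 22.0, 0.554 ± 0.442 and 9.55 ± 3.80 CPM. RCc2 was at 7.67 ± 3.23, 4.25 ± 0.0279 and 6.17 ± 1.86 CPM. The PR10 gene was at 91.5 ± 7.58, 24.5 ± 7.72 and 31.6 ± 18.1 CPM. The differences of RCc3 in both groups and of RCc2 in horizontal WT lay within the SD of vertical WT. These means show no rise of root-specific genes, but the question of root share is not settled. An iron response to the mutation or to orientation stays open as a hypothesis and was not tested.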

How the results depend on the processing

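The alternatives without crowded windows, without absent genes and with lists freed of potassium channels were chosen after the data were seen. Counts of calls are given for genotype vertical, genotype horizontal, orientation WT, orientation bta3-1 and interaction, whose reported values are 409, 385, 1079, 281 and 0. DESeq2 gave 744, 768, 1982, 857 and 25, with overlaps of 380 and 555 for genotype and orientation against 253 and 212. The series design names no covariate, so the replicate number was not a block in the main fit. Between groups, the differences of replicate 1 from replicate 2 correlated at 0.372, 0.0613, 0.293, 0.0369, 0.224 and 0.205, all positive. That 8 of 8 libraries correlated best with their own number follows from these signs with 2 libraries per group, and adds nothing. The third component (13.4%) also placed every replicate 1 library opposite every replicate 2 library. These values point to a shift shared by replicate number, which the main fit counts as spread. The fit with the replicate block gave 676, 811, 2757, 1038 and 8, with an orientation overlap of 722. Under it LAZY 1 passed for genotype in vertical seedlings (adjusted p = 0.00969) and for orientation in bta3-1 (0.0294), and the auxin biosynthesis (0.0745) and phosphate starvation (0.0648) lists did not pass for orientation in WT. Without a filter, orientation bta3-1 gave 521, the interaction 3 and the orientation overlap 356. Fitting only the 4 libraries gave 346 for orientation WT and 388 for orientation bta3-1, which turns the order of these counts. Without crowded windows the genotype counts were 183 and 158 with 96 shared, and without absent genes 196 and 195 with 100 shared. Of the reported calls, 146 and 153 lay in these windows and 127 and 128 were absent genes, and some of the remaining calls were lost too, because the same p-values were adjusted over the genes left. An adjusted p of 0.01 left overlaps of 151 and 21. With an estimated correlation 0 lists passed in every comparison, against 6, 4, 12, 13 and 8. The causes of the other changes were not tested. Leaving out 1 library gave 176 to 397, 169 to 452, 143 to 1231, 6 to 392 and 0 to 0 calls, overlaps of 155 to 223 and 6 to 231, and 4 to 8, 2 to 4, 7 to 13, 9 to 13 and 4 to 11 lists. Which libraries moved these by over 1.5 times is given with each comparison. DESeq2's size factors, robust dispersion and limma-trend stayed within 1.5 times for each count. The 126 named results, each a gene in a comparison, were checked in each setting that tested them, which left 125 with only the 4 libraries, 105 without crowded windows and 102 without absent genes, and no direction turned in these checks. Outside the fits that left out 1 library, 1045 of these checks kept their side of the threshold, 3 gained a call and 40 lost it, and in those fits 785 kept their side and 223 lost a call. The jasmonate list was lost without crowded windows (adjusted p = 0.17) in vertical seedlings. A pseudocount of 0.1 was meant for a table without counts and was not run. On simulated counts for genotype in vertical seedlings at this depth and number of libraries, edgeR recovered 15% and DESeq2 48% of 2-fold changes. The changed genes were drawn from those with a mean CPM above 1 on the log2 scale, and no shift by replicate number was simulated. Depth itself was not varied.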

Other observations

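Of the tests in this part, those of the gene lists were planned and the one on sequence differences was set before its result was seen. The tests of crowding, of deletions, of an even spread, of vertical WT replicate 2 and of the response in bta3-1 were chosen after the results were seen. For vertical WT replicate 2, a bound on the ratio of counts without that library was added after those counts and the result of the splits were known, and it turned the verdict from argued against to open.

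Of the 35 gene lists tested, 14 were called in no comparison. SAUR genes, which respond fast to auxin, came closest, lower in vertical bta3-1 (37 members, camera adjusted p = 0.0514), followed by root markers (21 members, 0.0743) and brassinosteroid genes (94 members, 0.0996). Starch synthesis genes, which fill the amyloplasts that sense gravity, had a lowest adjusted p of 0.124 over 28 members. Aux/IAA repressors (23 members) had 0.139, auxin transport genes (20 members) 0.219, expansins (26 members) 0.242, GH3 genes (9 members) 0.297, strigolactone genes (16 members) 0.424 and cytokinin response genes (7 members) 0.415. Light-harvesting proteins (51 members) had 0.172, cellulose synthases (40 members) 0.28 and KNOX and young shoot markers (14 members) 0.588. The tiller angle list itself (6 members) had 0.136.

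Genes called for genotype in both orientations were crowded: 18 windows of 1 Mb held 130 of 252 such genes on chromosomes 1 to 12. The spread over chromosomes had a chi-square of 348 (p = 1e-05 by multinomial simulation, the smallest that 100000 draws can give). The draws take genes as independent, which neighbouring genes need not be, so this p may be too small. The binomial tests of windows and the Fisher's exact tests take genes so too. Their p-values may be too small and the interval below too narrow. A response by genes spread like the tested genes is argued against as the whole source, since chromosome 10 held 5.61 times its expected number. Deletions in bta3-1 as the whole source are argued against by 16 genes of these windows absent from WT, beside 51 absent from bta3-1, where absent means 3 counts or fewer over the 4 libraries of a genotype and more than 100 in the other. Sequence differences between the lines may change which reads are counted or which genes are present: in 9 windows chosen by called genes with more than 3 counts in each genotype, 29 of 586 other genes were absent from a genotype in this sense, against 105 of 24578 elsewhere (Fisher's exact test, odds ratio 12.1, 95% interval 7.68 to 18.6, p = 4.77e-20). This is consistent with a difference in background between the lines, which the labels do not describe, and effects of the mutation on genes outside these windows stay open.

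Orientation called 1079 genes in WT and 281 in bta3-1, but 346 and 388 when only the 4 libraries of each contrast were fitted. The counts were 413 and 392 without vertical WT replicate 2, 222 and 178 without horizontal WT replicate 1, and 143 and 172 without horizontal WT replicate 2, while in the other 5 fits that left out 1 library the WT count was 3.23 to 136 times the bta3-1 count. The gap thus depends on these choices. To ask whether bta3-1 responds less, 1000 genes were chosen in 4 libraries and read in the other 4, and the ratio of the response in bta3-1 to that in WT was 0.48 to 1.11 with a median of 0.78. It was under 0.9 in 12 of 16 such splits, so a smaller response in bta3-1 stays open and cannot be told apart from equal responses with 2 libraries per group. Vertical WT replicate 2 as a source stays open too. The ratio was lower with it in 0 of 8 matched splits. Every split used that library, either to choose the genes or to be read, so the splits cannot decide. The gap in counts nearly closed without it, but it also narrowed or turned without either horizontal WT library, so this is not particular to it.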
